A study of Caenorhabditis elegans with 2 samples.

How the data were processed

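Whole L1 larvae of C. elegans strain OP18, which has the unc-119 mutant background and the integrated transgene wgIs18 with eGFP-tagged lin-39, were profiled by transcription factor ChIP-seq in 2 biological replicates, per the labels. The labels give a fragment size range of 150 to 350, without a unit, and 1 group, LIN-39-eGFP ChIP in L1 larvae. The antibody field of the labels names lin-39 and the description names the eGFP fusion. The replicate numbers were taken from the labels.

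Per the submitters' file notes deposited with each sample, the region lists were derived from alignments of the replicates and a control alignment, on the ce10 and ce11 builds. The control, the alignments and signal tracks were not analysed here. The aligner, the peak caller and the reproducibility cutoff are not given in the sources used here. The deposited lists are headerless narrowPeak tables: 30000 ranked regions for replicate 1, for replicate 2 and for both together (pooled), and a set of optimal peaks for both together. The deposited signal value of each region is the authors' own score relative to the control, with no stated scale. The deposited −log10 q of each region follows the narrowPeak definition; it saturates at 3.51 in the pooled list, where 1610 regions share the maximum, and all 1488 optimal peaks hold that maximum, so it was not used to rank them. The deposited summit offset of each region, in bp (another per-region number), placed the summit. Signal scales differ between lists (maximum 387.8 in replicate 1 and 231.3 in replicate 2), so replicates were compared by ranks within a list, overlaps and correlations, and raw signals of single peaks are given per replicate without being compared. Depth is unknown, since the lists give no read numbers; binomial intervals cover the sampling of peaks or genes only. The replicates shared 0 regions with identical coordinates, so they are separate lists.

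Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, on ce11 coordinates with the matching WBcel235 genome and the gene annotation of Ensembl release 115. All ce11 regions fell within the chromosome lengths. The ce10 lists were used only for counts, overlaps and correlations within that build; no coordinate was converted. For X share in ce10, ce11 lengths stood in.

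Replicate agreement was measured on the 1488 strongest regions of each replicate, the size of the optimal set, by overlaps of at least 1 bp, against 1000 circular shifts of replicate 2 within chromosomes. Summits were placed relative to protein-coding gene starts (2000 bp upstream to 500 bp downstream, nearest start) and to coding exons, UTRs, introns and intergenic sequence, in that order of precedence, again against 1000 circular shifts. Intergenic means outside protein-coding genes. Chromosome shares were tested with exact binomial tests against chromosome length. Target genes were compared with 25 gene lists by two-sided Fisher's exact tests against all 19973 protein-coding genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. In these lists 9 symbols had no protein-coding match and were left out, 6 of them in the heterochronic list, where most are microRNA or other noncoding genes. Motifs were sought on both strands within 100 bp of each summit and in windows 1000 bp to either side; the exact McNemar test used 1 side per peak, drawn with a fixed seed. Differences in median signal were tested with 100000 permutations, two-sided. Groups, the main tests, gene lists and most alternatives were fixed before the data were examined; the length of the stretch around lin-39 and the base composition of summits were looked at later, and the closing section names the other tests chosen later.

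Genes were named by a fixed rule: lin-39 and the other 5 Hox genes whatever their values; the 20 protein-coding genes with the strongest assigned peaks; from each list up to 4 members with the strongest assigned peaks; and members without a peak only in lists of 12 or fewer. Exact coordinates were given for the 10 strongest peaks and at the Hox genes. The remaining muscle genes, the neighbours of strong peaks outside promoter windows, snu-23 and the coordinate of the summit in unc-62 fall outside this rule and were added after their values were seen.

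Before use, the tests were tested on simulated data. With 20 simulated sets each of 1488 peaks, random placement passed 0.05 in 2 sets for the promoter share and 2 for the composite motif. Shuffled simulated signals passed it in 2 sets for the signal difference. The 200 peaks planted at gene starts, the motif planted in 10% of peaks and a signal raised by 20 in 250 peaks were called in 20 of 20. The main composite motif and signal differences in the data were smaller than the planted ones. Power at those sizes was not tested. Randomly placed peaks also lack the GC difference between summits and flanks seen in the data. Of 200 genes planted with a peak, 200 were recovered. These genes were drawn only from those without another protein-coding start nearby, so assignment among starts that share a window was not tested. Random target genes gave 1 call in 500 list tests, and 20 planted ribosomal protein genes were called in 20 of 20. Where 1041 shared regions were planted, 1042 were counted.

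Alternatives covered the window, the summit, merging of overlapping peaks, the gene assignment, the background, the number of peaks, the overlap required, the build, the motif window and flank, the signal scale, the lin-39 locus and each replicate's list alone. With 1 group of 2 samples, no outlier test and no contrast between groups applied.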

Results

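LIN-39 is a Hox transcription factor of the nematode Caenorhabditis elegans, known for patterning the mid-body, including the vulval precursor cells, ventral cord motor neurons and migrating neuroblasts. Its binding was profiled by chromatin immunoprecipitation and sequencing in whole L1 larvae, the first larval stage, of strain OP18, which carries an integrated transgene with an eGFP-tagged lin-39. There was 1 group, with 2 biological replicates per the labels, each a mixed-sex population. No second condition was part of the design, so the comparisons concern the agreement of the replicates and the identity of the bound regions. Each replicate came as a ranked list of 30000 regions, long on purpose, and a set of reproducible (optimal) peaks was given for both replicates together. Read numbers are not part of these lists, so the depth of each library is unknown and no interval below covers sequencing error. Signal values are the submitters' own peak scores and were used to rank peaks within a list.

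The optimal set held 1488 peaks on the ce11 build, with a median width of 340 bp (range 85 to 511). Their pooled signal had a median of 81.3 and ranged from 50.03 to 607.5. All 1488 were also the 1488 strongest regions of the pooled ranked list. The 10 strongest peaks comprised 6 on the X chromosome and 4 on autosomes. The strongest of all lay at X:14525639-14526149 (signal 607.5; 387.8 in replicate 1 and 217.7 in replicate 2), in intergenic sequence 745 bp upstream of nspc-17, a member of a nematode-specific peptide family. The next 5 were outside every promoter window. They lay at X:11093985-11094383 (signal 549.8, intergenic, 4003 bp from the start of W02H3.3), X:13700628-13701003 (528.3, intergenic, 6094 bp from K02D3.1), X:2996860-2997286 (497.9, in an intron of Y41G9A.17), X:9465707-9466046 (484.4, intergenic, 2538 bp from ZK899.6) and X:12362969-12363350 (478.7, intergenic, 1755 bp from F19H6.5).

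The 4 autosomal peaks among these 10 were all upstream of gene starts. The peak at II:10563457-10563706 (signal 471.5) was 179 bp upstream of cdc-48.1, which encodes a p97-type AAA ATPase. The peak at I:4172015-4172283 (468.4) was 585 bp upstream of egg-5, a pseudophosphatase gene of the oocyte-to-embryo transition. The peak at III:3867448-3867698 (452.9) was 285 bp upstream of rpl-3, which encodes a large-subunit ribosomal protein, and that at IV:4749952-4750201 (451.6) was 176 bp upstream of Y17G9B.5. All 10 ranked among the 27 strongest regions of each replicate.

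The first question was whether both replicates marked the same places. Of the 1488 strongest regions of replicate 1, 1013 (68.1%) overlapped one of the 1488 strongest regions of replicate 2 by at least 1 bp. Circular shifts of replicate 2 along the chromosomes gave a median of 14 shared regions and at most 28 in 1000 shifts (one-sided permutation p = 0.001 by circular shifts, the smallest that 1000 shifts can give). Of the optimal peaks, 1275 were among the strongest 1488 regions of replicate 1, 1156 were among those of replicate 2, and 1003 were among both. Over the 1480 optimal peaks with a region in both full lists, the replicate signals had a Spearman rho of 0.63 and a Pearson r of 0.68 on the log10 scale. This correlation runs across peaks, which are not independent replicates, and the peaks were selected on the pooled data. With an overlap of at least 50% of both regions required, rho was 0.52 over 1290 peaks. Ribosomal protein gene peaks illustrate the shared upper end: the rpl-3 peak was ranked 7 in replicate 1 and 12 in replicate 2, and the rpl-12 peak was ranked 22 and 13. At the lower end, the lin-28 peak was ranked 1016 in replicate 1 and 7346 in replicate 2, and the hlh-11 peak was ranked 731 in replicate 1 and had no overlapping region in replicate 2.

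**Figure D1:**
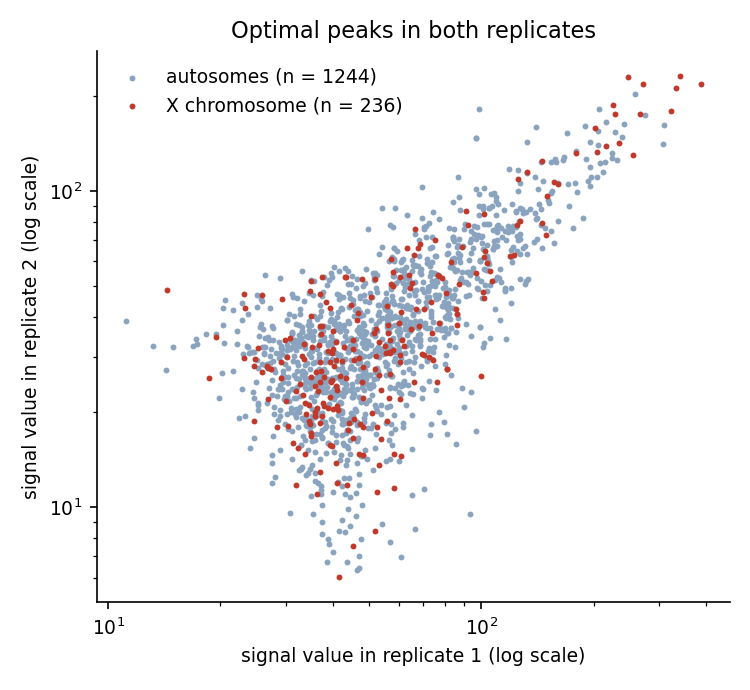
Each point is an optimal peak with an overlapping region in both replicates (1244 autosomal in blue, 236 on X in red); the axes are the signal values in replicate 1 and replicate 2, unitless and on log scales. The signals rise together (Spearman rho 0.63 over all 1480), and X peaks are among those with the highest signal in both replicates.

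The second question was where the peaks lie relative to genes. Bound regions were concentrated just upstream of protein-coding genes. The summits of 1049 of the 1488 peaks (70.5%, exact binomial 95% interval 68.1 to 72.8%) lay from 2000 bp upstream to 500 bp downstream of a protein-coding gene start. Circular shifts placed a median of 39.5% there and at most 44.5% (two-sided permutation p = 0.002 by circular shifts, the smallest that 1000 shifts can give; Benjamini-Hochberg adjusted 0.00233 over 7 kinds of place). These 1049 summits had a median position 194 bp upstream of the nearest start (quartiles 403 and 102 bp upstream), and 981 of them (93.5%) were upstream. The window itself reaches farther upstream than downstream, and no chance share was computed for this split. Intergenic sequence held 1107 summits (74.4%, against a shift median of 36.5%) and 5' UTRs held 47 (3.16% against 1.41%). Fewer summits than in the shifted sets fell in introns (297, 19.96% against 33.9%), coding exons (13, 0.874% against 24.7%) and 3' UTRs (22, 1.48% against 3.36%), each with the same adjusted p. A further 2 summits fell in exons without a coding or UTR annotation, the same share as the shift median. Peaks in promoter windows were stronger than the other 439, with median signals of 84.6 and 72.999 (two-sided permutation test, p = 6e-05).

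Peaks were spread unevenly over the chromosomes. Chromosome III held 267 peaks (17.9% of the set on 13.7% of the genome, two-sided exact binomial test, adjusted p = 1.8e-05 over 6 chromosomes) and chromosome I held 273 (18.3% on 15.03%, adjusted p = 0.000981). Chromosome V, the chromosome richest in chemoreceptor families, held 237 (15.9% on 20.9%, exact binomial test, adjusted p = 9.85e-06). The X chromosome also held 237 (15.9%, interval 14.1 to 17.9%, on 17.7% of the genome), which did not differ past the threshold (exact binomial p = 0.083, adjusted 0.124). Among the 744 strongest optimal peaks, X held 106 (14.2%, exact binomial test, unadjusted p = 0.0141). On X, 45.99% of the peaks lay in promoter windows, against 70.9 to 77.4% on the autosomes. No chance share was computed for X alone, but the median by circular shifts was 40.6% without X and 39.5% with it. The binomial test treats neighbouring peaks as independent.

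In all, 1026 protein-coding genes were the nearest start to a summit in their window, 5.14% of the 19973 on the nuclear chromosomes. A second start also had the summit in its window at 518 peaks, where the assignment to the nearest gene is uncertain. With every start in the window counted, 1653 genes were assigned. Among the 20 genes with the strongest assigned peaks, after nspc-17, cdc-48.1, egg-5, rpl-3 and Y17G9B.5 came F20B6.9 (signal 409.0), eelo-2 (400.6), Y22D7AL.10 (381.6), rpl-12 (381.0) and H41C03.3 (375.5). They were followed by rpb-11 (357.4), an RNA polymerase II subunit gene, rpl-15 (355.3), cox-5A (354.7), a cytochrome c oxidase subunit gene, rpl-35 (352.8), ddp-1 (349.8), a mitochondrial import gene, and mig-5 (346.9), a Dishevelled gene of the Wnt pathway. The last of the 20 were ent-2 (340.6), a nucleoside transporter gene, scpr-1 (327.0), Y55F3AR.2 (326.5) and dld-1 (319.8), which encodes dihydrolipoamide dehydrogenase. The peaks of these 20 genes were in intergenic sequence, 48 (rpl-12) to 1796 bp (F20B6.9) upstream of the assigned start.

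None of the 6 Hox genes had an optimal peak in its start window. For lin-39 (III:7528641-7536632, minus strand), the nearest optimal summit lay at III:7560005, 23373 bp away, and no region of any of the 3 ranked lists fell in the gene or within 5000 bp of it. The stretch without a pooled ranked region ran from III:7502291 to III:7559834, which is 57544 bp, and only 16 of the 29994 stretches between pooled regions were as long, counting this one. The same summit at III:7560005 (signal 86.4, rank 659) lay 1964 bp past the end of ceh-13 (III:7555660-7558041) in intergenic sequence. The start window of ceh-13 also lay within the stretch without a pooled ranked region. At mab-5 (III:7776835-7783454), 11 pooled regions lay in the gene or within 5000 bp, the strongest with a signal of 28.4 and rank 4815, and the nearest optimal summit, assigned to snu-23, was 5614 bp away. The best region at mab-5 was ranked 4063 in replicate 1 and 876 in replicate 2. The best pooled region at egl-5 (III:7814374-7817141) was ranked 18302, and php-3 (III:12074218-12077556) and nob-1 (III:12077793-12084316) shared a best region ranked 5181.

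Hox cofactor genes also lacked peaks in their start windows. The start was taken as the outer end of each gene, so starts of internal transcripts were not counted. Among the TALE homeobox genes, unc-62, the Meis/Prep homologue, had a peak at the summit V:4508008 (signal 193.5; 105.0 in replicate 1 and 88.2 in replicate 2), inside the gene at an annotated 5' UTR but outside the window of the gene start. The PBC-class genes ceh-20, ceh-40 and ceh-60 and the Meis-related psa-3 had their nearest optimal summits 6464, 42372, 61751 and 42548 bp away. With 0 of 11 genes, the share of Hox and TALE genes with a peak had an exact 95% upper limit of 28.5%, so depletion was not detectable in a list of this size (Fisher's exact test, adjusted p = 1). The count depends on the window: with 5000 bp upstream, 1 of 11 had an assigned peak (exact test, adjusted p = 0.725).

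**Figure D2:**
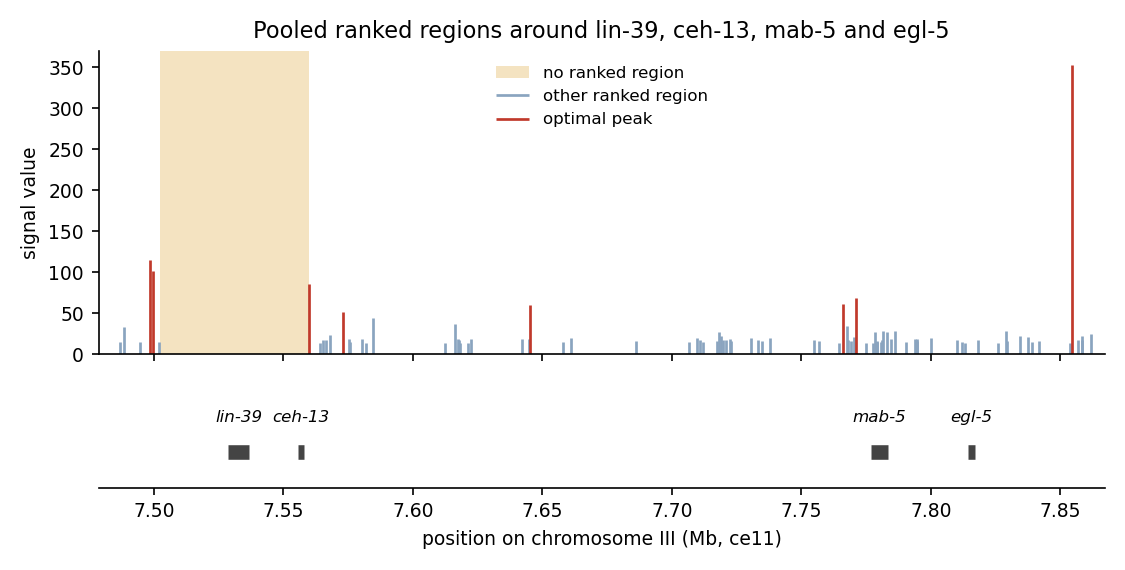
The upper panel shows the summits of the 87 pooled ranked regions over 388.5 kb of chromosome III (x axis, ce11 position in Mb) with their signal value (y axis, unitless); optimal peaks (8) are red and other ranked regions blue, and the shaded stretch of 57544 bp holds none. The lower panel shows the gene bodies of lin-39, ceh-13, mab-5 and egl-5; lin-39 and ceh-13 lie inside the shaded stretch.

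The third question was which gene groups the targets belong to. Of 25 lists fixed before the data were examined, 4 passed an adjusted p of 0.05 against all protein-coding genes (two-sided Fisher's exact test, Benjamini-Hochberg over the 25 lists). Ribosomal protein genes had peaks far more often than other genes: 31 of 76 (40.8%, interval 29.6 to 52.7%) against 3.9 expected, with an odds ratio of 13.1 (exact test, adjusted p = 1.8e-19). The strongest were rpl-3 (452.9), rpl-12 (381.0), rpl-15 (355.3) and rpl-35 (352.8). Body wall muscle genes had 7 of 30 (23.3%, interval 9.93 to 42.3%) against 1.54 expected (odds ratio 5.65, exact test, adjusted p = 0.00415). These were the myosin heavy chain genes myo-3 (signal 153.2, 1350 bp upstream) and unc-54 (62.3, 1655 bp upstream), the integrin-linked kinase gene pat-4 (79.8, 1555 bp upstream), the actin gene act-4 (60.8, 177 bp downstream), and unc-45, unc-27 and mup-2. The muscle call rested on replicate 1: among the 1488 strongest regions of replicate 2 the count was 4 (exact test, adjusted p = 0.291), and among those of replicate 1 it was 7 (adjusted p = 0.00381). It also ended with a window of 1000 bp upstream (4 of 30, odds ratio 3.12, exact test, adjusted p = 0.181) and in the 744 strongest peaks (1 of 30, odds ratio 1.21, adjusted p = 1). Without X, where fewer members remained, 4 of 20 had a peak (odds ratio 4.45, exact test, adjusted p = 0.0823).

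2 large families had fewer peaks than other genes. Chemoreceptor genes, which encode G protein-coupled receptors expressed mostly in sensory neurons, had 4 of 1276 (0.313%, interval 0.0855 to 0.801%) against 65.5 expected (odds ratio 0.0544, exact test, adjusted p = 3.43e-23). The 4 were srh-16 (signal 245.4), sri-5 (161.8), srd-43 (60.6) and srx-125 (50.6), and at srh-16 and sri-5 another gene start shared the peak. C-type lectin genes, many of them immune-response genes, had 0 of 240 (exact 95% upper limit 1.53%) against 12.3 expected (exact test, adjusted p = 4.3e-05). Members of these families lie in genomic clusters, so their genes are not independent draws. Neuropeptide genes had 1 of 140, ins-39 (signal 203.2), against 7.19 expected, short of the threshold (exact test, adjusted p = 0.0542). Nuclear hormone receptor genes had 7 of 269 (exact test, adjusted p = 0.285), led by nhr-119 (199.8), nhr-87 (170.8), nhr-47 (144.9) and nhr-10 (82.0). With every start in the window counted, both lists were past the threshold: neuropeptide genes with 2 of 140 (exact test, adjusted p = 0.00618) and nuclear hormone receptor genes with 9 of 269 (adjusted p = 0.00827).

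**Figure D3:**
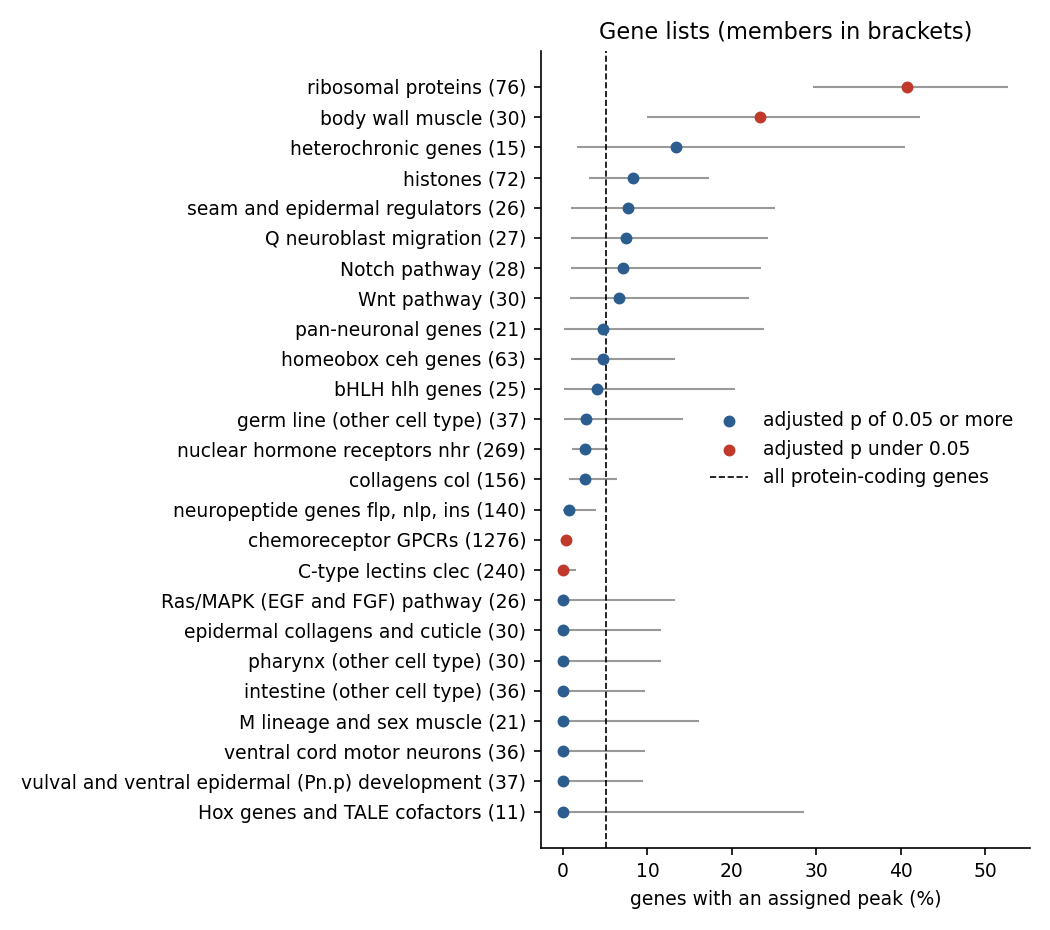
Each row is a gene list with its number of members; the point is the share of its genes with an assigned peak (x axis, percent), the bar its exact binomial 95% interval, and the dashed line the share of all protein-coding genes (5.14%). Ribosomal protein genes (40.8%) and body wall muscle genes (23.3%) sit above the line and chemoreceptor genes (0.313%) and C-type lectins (0%) below it, in red for an adjusted p under 0.05.

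The lists built around cells in which LIN-39 is known to act did not differ from the background. No gene of the vulval and ventral epidermal list (37 genes, 1.90 expected), the ventral cord motor neuron list (36 genes, 1.85 expected) or the M lineage and sex muscle list (21 genes, 1.08 expected) had an assigned peak, with adjusted p values of 0.571, 0.571 and 0.832. The exact 95% upper limits of these shares were 9.49%, 9.74% and 16.1%, so the background share of 5.14% is within reach of each. In the Q neuroblast migration list, 2 of 27 had a peak (exact test, adjusted p = 0.832): mig-5, whose peak lay in the windows of 2 gene starts, and pig-1 (signal 102.4), a MELK-like kinase gene of asymmetric neuroblast division.

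The remaining lists passed no test either. Of other developmental lists, seam and epidermal regulators had sop-2 (56.4) and lin-28 (51.4) of 26, the Wnt list mig-5 and wrm-1 (67.4) of 30, the Notch list sel-10 (83.02) and pen-2 (56.4) of 28, the heterochronic list ain-1 (54.97) and lin-28 of 15, and the Ras/MAPK list 0 of 26. Pan-neuronal genes had ric-19 (63.5) of 21. Homeobox ceh genes had ceh-38 (225.6), ceh-5 (177.7) and ceh-18 (63.5) of 63, and bHLH genes had hlh-11 (50.8) of 25. Histone genes had 6 of 72, led by his-37 (180.3), his-68 (153.1), his-31 (116.9) and his-60 (68.4), and col genes had 4 of 156, col-94 (187.2), col-63 (96.9), col-38 (78.2) and col-55 (71.2). Epidermal collagen and cuticle genes had 0 of 30. Of the lists for other cell types, the intestine had 0 of 36, the pharynx 0 of 30 and the germ line 1 of 37. The germ line gene was cgh-1 (115.1), which shared its peak with a second start. These counts do not set other cell types apart from the lists built around LIN-39, some of which also had no gene with a peak. Adjusted p values of all these lists were 0.571 or higher.

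The fourth question was whether Hox recognition sequences mark the summits. The composite site bound by Hox proteins with PBC cofactors, TGATNNAT, occurred within 100 bp of 253 of 1488 summits (17.003%, interval 15.1 to 19.01%) and in 15.3% of windows 1000 bp to either side, a difference of 1.75 percentage points (two-sided exact McNemar test, p = 0.178, adjusted 0.178 over 6 motifs). Within 50 bp of the summit the difference was 2.55 points (exact test, unadjusted p = 0.00923). The homeodomain core TAATTA occurred at 116 summits (7.8% against 9.14% in flanks, exact test, p = 0.0531, adjusted 0.0637). Its difference was -1.85 points within 50 bp (exact test, unadjusted p = 0.000396) and 2.65 points within 200 bp (p = 0.15). Rearranged sequences of the same bases were rarer at summits than in flanks. TAGTNNAT stood at 5.71% against 7.76% and TTAGNNAT at 7.39% against 9.98% (exact test, both adjusted p = 0.0502). TTAATA stood at 11.02% against 15.1% (exact test, adjusted p = 0.00294) and TATAAT at 7.86% against 14.1% (adjusted p = 2.9e-07). Summit windows were also richer in G and C, with a median GC content of 40.3% against 36.3% in flanks. Peaks with a composite site were not stronger than those without, with median signals of 80.5 over 253 peaks and 81.3 over 1235 (two-sided permutation test, p = 0.761).

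**Figure D4:**
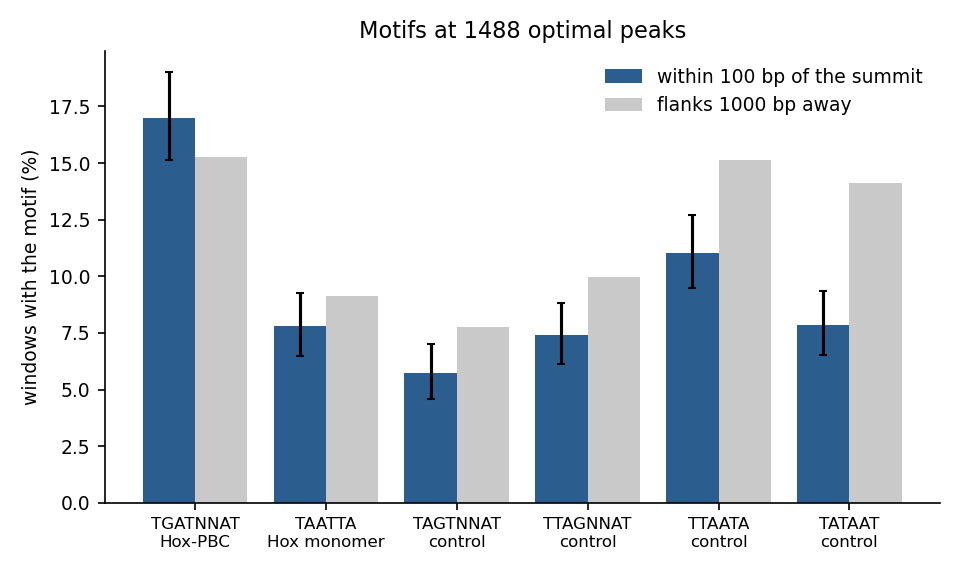
Bars give the share of windows (y axis, percent) that hold each motif on either strand, within 100 bp of the 1488 summits (blue, with exact binomial 95% intervals) and in flanks 1000 bp away (grey, mean of both sides). The composite Hox-PBC site stands at 17.003% against 15.3%, and each of the 4 control motifs is lower at summits than in flanks.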

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

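No paired analysis was possible because the design has 1 group. The alternatives without X, on peaks outside promoter windows, on X or the autosomes alone and with large families out of the background were chosen after seeing the data; the others were fixed before. The optimal peak count, the replicate overlap (52.8 to 73.8% shared) and the promoter share (63.9 to 84.0%) kept their direction and their side of the threshold, or stayed within 1.5 times, under each alternative run, as did the higher signal of promoter peaks. Leaving out a replicate (using the other one's strongest regions) gave promoter shares of 68.1 to 69.7%, X shares of 16.1 to 16.9%, target gene counts of 996 to 1011, 3 to 4 lists past the threshold, composite motif differences of 1.68 to 2.25 points (exact test, p = 0.209 and 0.0473) and monomer differences of -0.874 to -0.605 points. Only 802 and 880 of the 1026 target genes were kept in these lists. Among values that moved or crossed the threshold, with the cause not tested unless stated: the replicate Spearman rho was 0.52 with an overlap of at least 50% of both regions; the target gene count was 1653 with every start counted and 553 with the 744 strongest peaks, both by construction; the X share was 14.2% among the 744 strongest peaks (exact test, p = 0.0141); the composite motif difference was 2.55 points within 50 bp (p = 0.00923) and 8.2 points outside promoter windows (p = 0.0305); the monomer difference was -1.85 points within 50 bp (p = 0.000396) and turned to 2.65 points within 200 bp (p = 0.15). Among the lists past the threshold and those built around LIN-39, the direction against the background turned, short of the threshold, for Hox and TALE genes (1 gene, exact test, adjusted p = 0.725) and M lineage genes (3 genes, adjusted p = 0.456) with 5000 bp upstream, and for Q neuroblast genes (2 genes, adjusted p = 1) with every start counted. Several of the remaining lists also turned short of the threshold. Examples are Ras/MAPK genes with 5000 bp upstream (2 of 26, odds ratio 1.31) and Wnt genes without replicate 1 (1 of 30, odds ratio 0.657). The ribosomal protein, chemoreceptor and lectin calls stayed past the threshold in the same direction in each alternative run, though counts moved: with every start counted, 53 ribosomal protein genes (odds ratio 26.4) and 11 chemoreceptor genes had a peak, and with 5000 bp upstream 9 chemoreceptor genes did; the muscle call was lost in 4. Neuropeptide genes passed the threshold without X (0 of 106, exact test, adjusted p = 0.0446) and with large families out of the background (1 of 140, adjusted p = 0.0368). A stricter value of the reproducibility column was not run, because it is constant over the optimal peaks. The unknown depth limits what the lack of a peak says.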

Other observations

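The tests of short RNA genes, of GCGCAGGG and GAGACGCA in the optimal peaks, of the number of X peaks among the 20 strongest, of the composite motif by place, of the stretch around lin-39, the sign test of the repeat share and the comparison of the composite motif with its controls were chosen after the results were seen. The sequence GAGACGCA was picked from a search over all sequences of its length in these same peaks, and GCGCAGGG was recalled from known biology once strong X peaks had been seen. More summits than in shifted sets lay near the starts of short structural RNA genes. The shifts take no account of the general concentration of summits near gene starts. No comparison with the starts of other genes was run, so these RNA genes cannot be called singled out. Of the 1488 summits, 102 (6.85%) lay within 250 bp of the start of a tRNA, snoRNA or snRNA gene, against a median of 0.47% and at most 1.21% in 1000 circular shifts (two-sided permutation p = 0.002 by circular shifts, the smallest that 1000 shifts can give, adjusted 0.003 over 9 classes). By class, 50 summits lay at snoRNA genes (3.36% against 0.134%), 29 at tRNA genes (1.95% against 0.269%) and 23 at snRNA genes (1.55% against 0.0672%), and 7 lay at microRNA genes (0.47% against 0.134%). Long intergenic RNA genes were also past the threshold, with 6 summits (0.403% against 0.0672%, permutation by circular shifts, adjusted p = 0.0128), while pseudogenes (11 summits) and rRNA genes (0) were not. The piRNA genes had 28, fewer than the shift median (1.88% against 3.43%, permutation by circular shifts, adjusted p = 0.003).

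A GA-rich sequence, GAGACGCA, occurred within 100 bp of 191 of 1488 summits (12.8%) and in 1.21% of flanks (exact McNemar p = 3.7e-38, which takes no account of the search that picked the sequence). It was present at 12.7% of promoter peaks and 13.2% of other peaks; outside promoter windows it was at 9 of 128 peaks on X (7.03%) and 49 of 311 on the autosomes (15.8%), and these differences were not tested. On X it occurred at 24 of 237 summits (10.1%), and on the autosomes at 167 of 1251 (13.3%).

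The composite Hox-PBC site was commoner at peaks outside the promoter windows of protein-coding genes. Starts of internal transcripts and of noncoding genes count as outside these windows, so such peaks need not be far from a promoter. Outside promoter windows, 111 of 439 summits had it (25.3%) against 17.1% of flanks, an excess of 8.2 points (exact McNemar p = 0.0305, adjusted 0.0739 over all motifs and subsets); inside them, 142 of 1049 had it (13.5%) against 14.5%. The difference of the excesses was 9.15 points (two-sided permutation p = 0.00045). The same difference for the rearranged controls was 2.58 points for TAGTNNAT (-0.228 outside and -2.81 inside, permutation p = 0.141) and -1.66 points for TTAGNNAT (-3.76 outside and -2.1 inside, permutation p = 0.395). The composite site exceeded them by 6.57 points (permutation p = 0.0335) and 10.8 points (permutation p = 0.00062). It was also the commoner motif, with 17.1% of flanks outside promoter windows against 7.97% for TAGTNNAT and 11.7% for TTAGNNAT. A commoner motif gives more points for the same proportional change. TAGTNNAT leaned the same way, from 4.86% at summits against 7.67% in flanks inside to 7.74% against 7.97% outside. The comparison in points therefore cannot decide whether base composition is the source. Many homeodomain proteins read similar sequences, and no other factor was compared here.

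Of the 20 strongest peaks, 11 were on X, against 3.19 expected from the X share of the optimal peaks (exact hypergeometric p = 5.9e-05), and 9 of the 11 lay outside promoter windows. The tables argue against 1 replicate carrying them, since 20 of the 20 strongest X peaks were among the 1488 strongest regions of both replicates. Repeats and high GC content stay open. The median share of soft-masked bases in the 20 was 18.4%, between the preset bounds of 10% and 50%. In the other peaks it was 27.6% (permutation p = 0.19). The maximum in the 20 was 37.8%, and 0 of the 20 were above 50% (exact sign test p = 1.9e-06). That sign test says little about X peaks, since the median of all optimal peaks, 27.4%, was also below 50%. The median GC of the 20 was 39.3% against 40.3% in the other peaks (permutation p = 0.641). A candidate explanation is recruitment sites of the X dosage compensation complex, whose known motif contains GCGCAGGG: this core occurred at 14 of 237 X summits (exact McNemar p = 0.000122), in 0 of their flanks and at 0 of 1251 autosomal summits, and 9 of the 14 were among the 20 strongest X peaks. The predicted excess in X regions below the threshold was not found (0.14% at summits and 0.14% in flanks, exact McNemar p = 0.629). Within the optimal X peaks, the core was at 45% of the 20 strongest and 2.3% of the other 217. Sites that are few and strong would leave no excess below the threshold, so that test cannot decide. The value below the threshold and the GC value each met the preset bound against its explanation. The demand that they do so by more than chance was applied to both after their values were seen, which leaves both open.

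Few genes of the lists built around LIN-39 had a peak at their start, 2 of 122 over 5 lists, against a median of 6 in random lists (two-sided permutation p = 0.0874) and of 5 in lists matched on upstream length (p = 0.167), so a chance deficit is not excluded. A window that is too narrow stays open: with the gene and 5000 bp either side, 27 genes held an optimal peak, against a median of 29 and a 5th percentile of 22. So does the threshold: with the 5000 strongest pooled regions, 13 genes had an assigned region, against a median of 15 and a 5th percentile of 10. For lin-39 itself, extra copies carried by the transgene could raise the control and hide regions, since the stretch of 57544 bp without a ranked region was shared by the replicates (50386 and 45551 bp) and had 10 and 11 pooled regions in the 40 kb beyond its ends. The left ends of the stretch differed by more than the 5 kb that the test allowed, so this explanation stays open. So does binding in few cells of the whole larva, which was not tested. The start window of ceh-13 lies in the same stretch, so its lack of a peak carries the same limit.

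The ribosomal protein genes were not singled out by promoter GC content: 31 had a peak, against a median of 4 and a maximum of 13 in 10000 random lists matched on promoter GC (two-sided permutation p = 0.0002, the smallest that 10000 lists can give). Peaks at active promoters in general may be a source of this group; no expression or open-chromatin data were used here to test it. Binding shared with other factors, weak enrichment of the target and a mislabelled sample were not tested for any of these patterns, because the series has 1 target and 1 condition.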
